A study of Homo sapiens with 42 samples.

How the data were processed

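RNA levels were taken from 1 deposited table for 42 libraries of HAP1 cells in 10 groups (5 genotypes, each in media or with 200 µM BSO for 48 h, begun after 4 h). Its values are the authors' normalized signal: per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to GRCh38 (hg38) with HISAT2, handled with SAMtools, counted per gene with featureCounts and normalized with DESeq2. The versions of those tools are not given in the sources used here, nor is the strand setting of the counting. Total RNA was extracted and libraries were prepared with standard Illumina protocols, per the labels' protocols.

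The table held 30182 entries, 20515 with a gene symbol and 9667 without (0.868% to 1.25% of a library's reads). Dividing each column by its smallest step gave whole reads for 100% of the values (relative tolerance 1e-06). This gave library sizes and size factors (1 read had a value of 0.941 to 1.04). The smallest total of an entry over all libraries was 10 reads. The libraries held 26.8 M to 30.7 M reads, 17861 to 18505 genes with reads, and 4.54% to 6.23% of reads in their 10 most abundant genes. Within groups the spread between replicates exceeded counting noise (chi-square per degree of freedom of 2.97 to 52.2 over pairs of libraries of a group, those of wt including pairs across the label sets).

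The groups, the comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined; alternatives chosen after seeing the data are named as such. The main test was limma with an intensity trend (limma 3.58.1, R 4.3.3) on log2(value + 1) for 14331 named genes with a mean of 10 or more over all libraries. It was fitted to all 42 libraries with a term for each of the 10 groups and 1 for the label set (sample names with or without a final A or B). All wt groups hold both label sets, whereas neil1 and neil2 hold only the unlettered and neil3 and neil123 only the lettered one. Benjamini-Hochberg adjusted p under 0.05 was the threshold in each of 13 comparisons: each knockout against wt in media, BSO against media in each genotype, and the difference between the BSO change in each knockout and that in wt. Printed media means of wt are over the wt libraries of the knockout's own label set.

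Replicate names pair each BSO library with a media library. Over 21 pairs the deviations from the group means of the members of a pair correlated across genes with r = 0.375 to 0.849 (residuals of the fit: -0.0793 to 0.849), and 15 of 21 BSO libraries correlated best with their own media library. With every r from the group means above 0.1, the names were taken to pair the libraries. The pairing is less sure in wt, where the group means join both label sets: the residuals of wt 1.1 (-0.0793) and 1.3 (0.0554) gave no r above 0.1, and 1 of 7 BSO libraries correlated best with its own media library. A fit with the replicate name as a block is given beside a result with BSO wherever it changed a call or moved a count by more than 1.5 times.

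Gene lists were fixed beforehand: 35 lists with 708 entries, of which 669 (616 genes) were in the table and 614 were tested. They cover glutathione and other antioxidant systems, stress responses, cell death, lipid and energy metabolism, DNA repair and demethylation, immediate-early and immune genes, and markers of cell states. Lists were tested against all other genes with limma's camera, with the preset correlation of 0.01 and with the correlation estimated from the data; adjusted p is over the lists of a comparison. A count called adjusted over the list alone uses only the genes of that list.

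Named genes follow a rule also fixed beforehand. For each comparison they are NEIL1, NEIL2 and NEIL3, and the 10 highest rises and 10 largest falls past the threshold (6 and 6 for BSO in each knockout, 4 and 4 for the differences) with a mean of 50 or more in the higher group, a symbol that is not a locus or clone identifier, and the same direction in every replicate. Members of the lists follow (up to 4 per list with the largest change among those past the threshold, and 12 glutathione and ferroptosis genes whatever their test), and genes called alike in all 4 knockouts. The report prefers among these the genes whose call did not depend on 1 library. Some genes are not reported here. Genes set apart only by the difference between the label sets of wt (CENPF among them) were chosen after the values were seen. Genes that share reads with near-identical copies (RTL8A, RTL8B and RTL8C, AKR1C1, AKR1C2 and AKR1C3, metallothioneins, and pseudogenes of FTH1) are uncertain, and so are antisense genes, such as HAGLR.

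Alternatives fixed beforehand were the fit without the label set, the replicate block (in media the letter of the name; not for the gene lists), the line name as a random block (correlation within lines 0.206), 1 mean per line, only the compared groups, other pseudocounts (0.5 and 5), other filters (a mean of 50 or more, and all genes with a value), columns scaled to equal totals, quantile normalization, robust variance moderation, edgeR 4.0.16 (quasi-likelihood test, with TMM or the recovered size factors), DESeq2 1.42.0 on whole reads, and each library left out in turn. Alternatives added after seeing the data were the replicate block in the tests of gene lists, leaving out each line, leaving out the unlettered wt libraries of lines 1.1 and 1.3, each label set of wt alone, removal of the trend with exon length, and combinations of these with the replicate block. Exon lengths came from GENCODE 29 and were found for 95.65% (13707) of the genes tested. Positions for the chromosome regions came from RefSeq genes and were found for 96.9% (13888).

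For overlaps between knockouts, 50 simulations drew unchanged groups sharing wt libraries, either all or those of each label set as separate controls. Splits of the libraries of a comparison, at most 100, were refitted to see how often as many genes pass. The scripts were tested on simulated reads with the means, library sizes and spread of the real libraries and 200 changed genes among 14331. Of 100 genes changed 1.5-fold, limma found 65 to 78 in media, 70 to 81 with BSO and 54 to 64 as differences in the BSO response, and of 100 changed 2-fold 84 to 88, 75 to 94 and 74 to 84, with 5 to 13, 6 to 10 and 6 to 9 false calls. With the replicate block the ranges for BSO were 67 to 77 and 74 to 96 with 4 to 14 false calls, and for differences 54 to 63 and 73 to 85 with 1 to 10. For BSO in wt, edgeR found 78 and 95 and DESeq2 79 and 95. Reads were recovered exactly for 100% of simulated values, camera called the 1 changed list and 0 of 20 unchanged ones. A trend with length of rho = -0.549 was reduced to 0.0041. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.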

Results

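RNA was profiled in 42 libraries of the human near-haploid line HAP1, from wild type (wt) cells and from lines labelled as lacking the DNA glycosylases NEIL1 (neil1), NEIL2 (neil2), NEIL3 (neil3) or all of them (neil123), each kept in media or given 200 µM buthionine sulfoximine (BSO) for 48 h. BSO inhibits glutamate-cysteine ligase, the enzyme that starts glutathione synthesis. There were 7 wt, 3 neil1, 3 neil2, 4 neil3 and 4 neil123 libraries per treatment. The 18 libraries of the unlettered label set (3 wt per treatment, neil1 and neil2) held 29.9 M to 30.7 M reads each, and the 24 of the lettered set (4 wt per treatment, neil3 and neil123) 26.8 M to 28.7 M. Mitochondrially encoded genes took 1.70% to 4.66% of the reads of a library. Levels are given as mean ± SD in normalized read counts, and changes as log2 differences ± standard error with limma's adjusted p over 14331 genes. In media the printed wt means, and n beside them, are over the wt libraries of the knockout's own label set. Log2 differences, errors and p come from 1 fit to all 42 libraries with a term for the label set. Nothing beyond the labels says that replicates were separate cultures (all labels but those of unlettered wt libraries name biological replicates), so each p measures the spread between these samples, which may be technical.

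**Figure D1:**
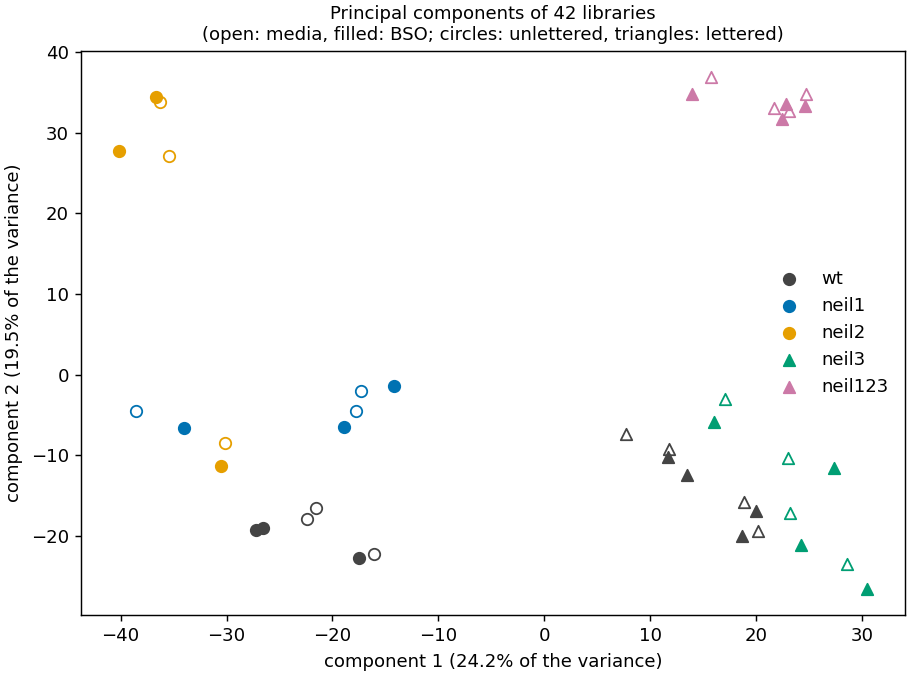
First and second principal components of the log2 values of all 42 libraries (axes: component scores, with 24.2% and 19.5% of the variance; 1 point per library, coloured by genotype, open for media and filled for BSO, circles for the unlettered and triangles for the lettered set). The first component separates the label sets: unlettered libraries lie between -40.2 and -14.2 and lettered ones between 7.70 and 30.5.

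The RNA of the targeted genes was examined first, as a check of the labels. NEIL2 (chr8, 11769710, 11787345), a glycosylase for oxidized bases in transcribed DNA, was lower in neil2 (311±14.7 against 554±63.2, n = 3 and 3; -0.85±0.09, adjusted p = 4.32e-08) and in neil123 (224±12.4 against 395±27.7, n = 4 and 4; -0.79±0.08, adjusted p = 3.18e-09). NEIL3 (chr4, 177309874, 177371268), which acts on single-stranded and crosslinked DNA, was lower in neil123 (424±39.6 against 640±35.2, n = 4 and 4; -0.61±0.09, adjusted p = 2.13e-05). In neil3 the drop in NEIL3 did not pass (520±106 against 640±35.2; -0.34±0.09, adjusted p = 0.0982): line 1 had 449 and 410, line 2 had 614 and 607, and the change was -0.59 without line 2 and -0.083 without line 1 (adjusted p = 0.889). NEIL1 (chr15, 75347039, 75357115), which removes oxidized bases ahead of replication, did not pass in lines labelled neil1 (386±116 against 355±46.6, n = 3 and 3; 0.13±0.16, adjusted p = 0.842) or in neil123 (987±109 against 852±92.2; 0.17±0.14, adjusted p = 0.516). Without the label-set term it was -0.635 (adjusted p = 0.188) and 0.752 (adjusted p = 0.0985), and in neil1 without line 13, which leaves 1 library, -0.263 (adjusted p = 0.528). The RNA level therefore does not check the neil1 label, nor the NEIL1 part of neil123, and a frameshift that leaves the RNA in place would not be seen here. NEIL1 was higher in neil2 (562±83.5 against 355±46.6; 0.71±0.16, adjusted p = 0.00506), a call lost without neil2 rep11.2 (0.60) and reversed without the label-set term (-0.06). NEIL1 differed more between the wt label sets (310 to 403 unlettered, 774 to 974.7 lettered) than between any knockout and its own wt libraries.

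**Figure D2:**
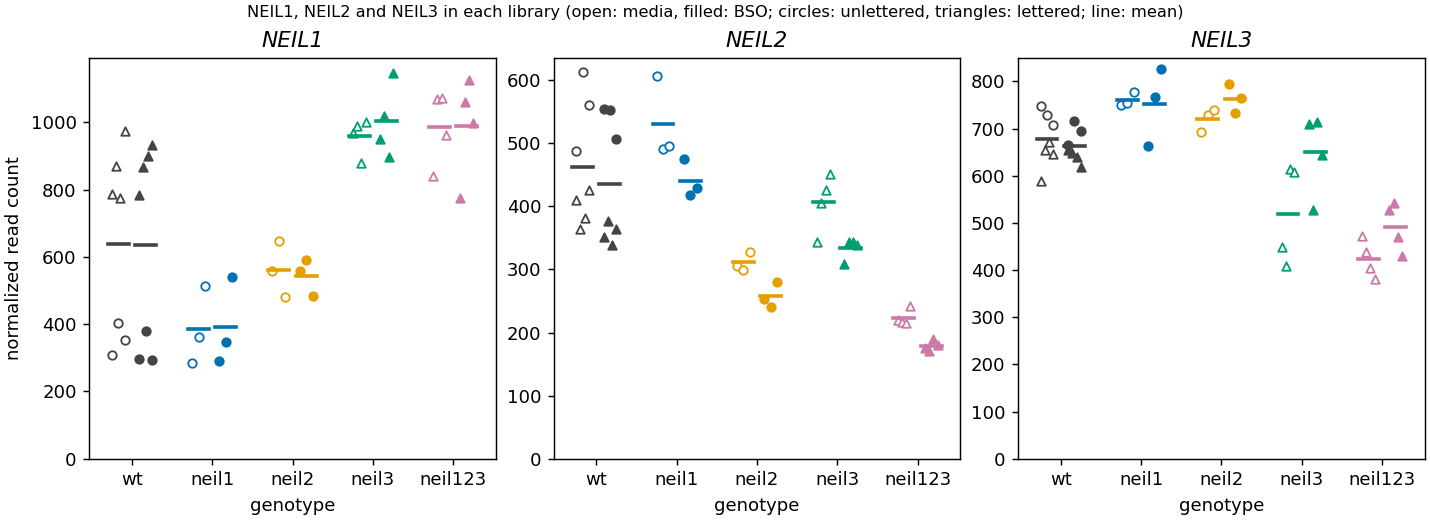
NEIL1, NEIL2 and NEIL3 in each library (vertical axis: normalized read count from 0; horizontal axis: genotype; 1 point per library, open for media and filled for BSO, circles unlettered and triangles lettered; line: mean). In media NEIL2 averages 311 in neil2 and 224 in neil123, against 554 and 395 in the wt libraries of the same set, whereas NEIL1 averages 386 in libraries labelled neil1 against 355.

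In media few genes differed from wt in the lines labelled neil1. HSD17B14, a dehydrogenase of steroids and small alcohols, rose from 56.2±9.58 to 149.6±17.5 (1.42±0.21, adjusted p = 0.000219, n = 3 and 3). The HOXD-cluster antisense RNA HAGLR, uncertain because the strand of counting is not known, rose from 23.9±6.13 to 64.7±14.6 (1.37±0.24, adjusted p = 0.00301). TCEAL8, a small nuclear protein of the transcription elongation factor A-like family, fell from 95.3±21.3 to 5.26±3.14 (-3.92±0.62, adjusted p = 0.000799). RTL8B, a retrotransposon-derived gene, was lower by -2.48±0.32 (adjusted p = 6.6e-05), which is uncertain because it shares reads with RTL8A and RTL8C. NQO1, the quinone reductase controlled by NRF2, did not pass (3467±134 against 2346±148; 0.53±0.13, adjusted p = 0.0539), although leaving out the wt library 1.3A brought it past the threshold at 0.56.

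In all, 29 genes rose and 21 fell in libraries labelled neil1, 10 and 16 of them 2-fold or more, and 14281 did not pass. Among the gene lists fixed beforehand, camera placed ATF4 targets higher (adjusted p = 0.000163, and adjusted p = 0.967 with an estimated correlation; 0 of 37 passed) and the cell cycle list higher (adjusted p = 0.0362, and adjusted p = 0.967 with an estimated correlation; 0 of 30). Mitochondrially encoded respiratory subunits were placed lower (adjusted p = 0.00945, and adjusted p = 0.967 with an estimated correlation; 0 of 13), as were interferon-stimulated genes (adjusted p = 0.0497, and adjusted p = 0.809 with an estimated correlation; 0 of 22 passed over all genes, 1 fell when adjusted over the list alone). The glutathione genes GCLC, GCLM, GSS, SLC7A11, GPX4 and GSR did not pass. The count of 50 became 19 without wt 1.1, 33 without wt 1.3, 24 without wt p1, 23 without neil1 rep13.1 and 25 without neil1 rep13.2. Of 25 named genes called, 6 kept the call whichever of 10 libraries was left out, among them the 4 named as changed in the paragraph above. With 1 mean per line, since libraries of a line correlate, the count was 10 and those 4 kept their call.

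A regional difference, looked for after the values were seen, set apart lines 12 and 13 of neil1, as inferred from the replicate names. Line 12 had 1 library per treatment. Its 315 genes of chromosome 15 beyond 50 Mb had a median log2 difference from wt of -0.142 in media and -0.137 with BSO. The 95% interval in media (-0.180 to -0.119) is over genes, not libraries. Of these genes 74.9% and 82.9% were lower than in wt. Line 13 had medians of -0.0056 and 0.0148. The first 50 Mb of the chromosome (-0.0201 and 0.007) and the other chromosomes (0.0306 and 0.0164) showed no such difference in line 12. NEIL1 lies within this stretch: line 12 had 284 in media, and line 13 had 361 and 513.

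**Figure D3:**
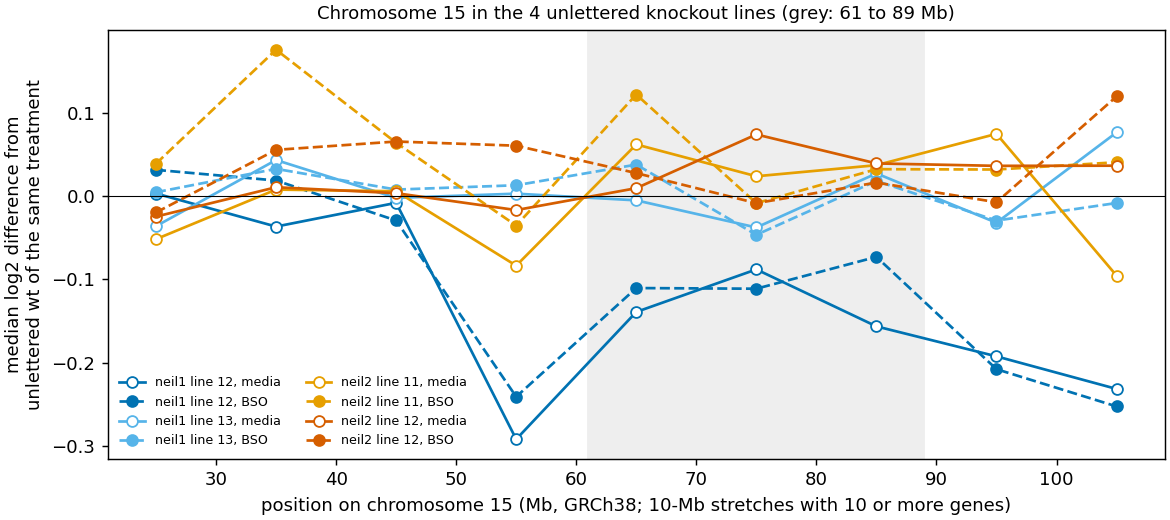
Median log2 difference from unlettered wt libraries of the same treatment (vertical axis) along chromosome 15 (horizontal axis: position in Mb, GRCh38) in the 4 unlettered knockout lines; each point is the median over the genes of a 10-Mb stretch, open for media and filled for BSO, and grey marks 61 to 89 Mb. The 2 libraries of neil1 line 12 lie below all others beyond 50 Mb, with medians over that part of -0.142 in media and -0.137 with BSO.

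Lines labelled neil2 differed from wt in media by many genes, in both directions. CHMP4C, a membrane-scission subunit that guards abscission, rose from 2.21 to 269.5±28.3 (6.76±1.26, adjusted p = 0.00086, n = 3 and 3). CGAS, the cytosolic DNA sensor, fell from 424±26.0 to 63.5±107 (-5.33±0.92, adjusted p = 0.000367). CGAS fell mostly in line 11: by -7.43 without line 12 (rep12) and by -1.14 without line 11, which leaves 1 library. The interferon-induced OAS2 fell from 148±28.7 to 48.6±10.4 (-1.64±0.40, adjusted p = 0.00759). BMP2, a ligand of the bone morphogenetic family, fell from 87.8±36.6 to 0.322±0.558 (-5.97±1.01, adjusted p = 0.000269). The interleukin receptor IL12RB2 fell from 116±24.0 to 7.13±3.0 (-3.92±0.23, adjusted p = 1.36e-14). The eye and neural regulator PAX6 fell from 216±25.3 to 62.7±20.6 (-1.85±0.34, adjusted p = 0.000676). Of genes that handle glutathione, the transferase GSTM2 rose from 42.7±9.74 to 199±89.6 (2.11±0.31, adjusted p = 4.14e-05; 1.33 without line 11, which did not pass) and the exporter ABCC5 rose from 1071±64.6 to 1379±63.3 (0.43±0.09, adjusted p = 0.00182). SAT1, a polyamine acetyltransferase linked to ferroptosis, rose by 0.58±0.11 (adjusted p = 0.00113). CFLAR, which blocks caspase-8, fell from 947±70.9 to 695±27.1 (-0.39±0.09, adjusted p = 0.00385).

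Counted over all genes, 673 rose and 835 fell in neil2 (90 and 220 of them 2-fold or more), and 12823 did not pass. GCLC, GCLM, GSS, SLC7A11, GPX4 and GSR did not pass. By camera 0 of 35 lists stood apart. Within lists, 3 glycolysis and hypoxia genes rose and 1 fell of 29 (3 and 2 adjusted over the list alone), and 2 interferon-stimulated genes fell of 22. Of 26 base excision repair genes 2 rose and 2 fell, NEIL2 among the latter. The count of 1508 became 927 without wt 1.1, 755 without neil2 rep11.1 and 306 without neil2 rep11.2. Without line 11 it was 113, with 1 neil2 library that was taken to vary like the other groups. Of 70 named genes called, 26 kept the call whichever of 10 libraries was left out, among them all those named as changed in the paragraph above. With 1 mean per line the count was 828, and of those genes CGAS lost its call.

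Few genes differed from wt in media in lines labelled neil3. BMP7, a bone morphogenetic ligand, rose from 327±100 to 1696±191 (2.44±0.50, adjusted p = 0.00652, n = 4 and 4), and the laminin chain LAMC3 rose from 139.5±16.3 to 452±24.7 (1.69±0.27, adjusted p = 0.000325). FUZ, a planar polarity protein needed for cilia, rose from 124±20.4 to 325±31.2 (1.36±0.24, adjusted p = 0.00122). The ETS factor FLI1 rose by 1.80±0.34 (adjusted p = 0.00221) and the membrane protein SHISA4 by 2.12±0.37 (adjusted p = 0.000785). TCEAL9, of the same family as TCEAL8, fell from 586±146 to 1.55±1.99 (-8.21±0.67, adjusted p = 1.44e-10). GABRA5, a subunit of GABA receptors, fell from 564±162 to 7.02±8.76 (-7.15±0.82, adjusted p = 4.73e-07). The zinc finger gene ZNF329 fell from 136.5±20.8 to 11.8±3.44 (-3.53±0.38, adjusted p = 1.96e-07), and LYL1, a regulator of blood cells, fell from 69.3±11.4 to 17.4±9.27 (-2.12±0.33, adjusted p = 0.000254). The mesenchymal regulator ZEB2 fell from 1135±56.4 to 973±60.4 (-0.26±0.05, adjusted p = 0.00371).

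Altogether 37 genes rose and 46 fell in neil3 (16 and 30 of them 2-fold or more), and 14248 did not pass. Neural markers were placed lower by camera (adjusted p = 0.00204, and adjusted p = 0.0108 with an estimated correlation; 0 of 12 passed, 1 fell when adjusted over the list alone; list median -0.70), and so were blood cell markers (adjusted p = 0.00289, and adjusted p = 0.0159 with an estimated correlation; LYL1 alone of 8 passed, 2 fell when adjusted over the list alone). Immediate-early genes (adjusted p = 0.00112, and adjusted p = 0.0984 with an estimated correlation; 0 of 20 passed, 2 fell when adjusted over the list alone), interferon-stimulated genes (adjusted p = 0.0344, and adjusted p = 0.16 with an estimated correlation; 0 of 22, 3 fell over the list alone) and ATF4 targets (adjusted p = 0.0365, and adjusted p = 0.857 with an estimated correlation; 0 of 37) were placed lower only with the preset correlation. GCLC, GCLM, GSS, SLC7A11, GPX4, GSR and NQO1 did not pass. No library left out moved the count by more than 1.5 times, whereas without line 1 it was 159 and without line 2 it was 249. Of 27 named genes called, 19 kept the call whichever of 11 libraries was left out, those of the paragraph above included. With 1 mean per line the count of 83 was 13. Of the genes of that paragraph TCEAL9, GABRA5, ZNF329 and LYL1 kept theirs, whereas BMP7, LAMC3, FUZ, FLI1, SHISA4 and ZEB2 did not.

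Lines labelled neil123 differed from wt in media by many genes. COL5A2, a fibrillar collagen chain, rose from 306±146 to 3861±1061 (3.75±0.58, adjusted p = 2.75e-05, n = 4 and 4), and the progesterone receptor PGR rose from 27.7±2.29 to 619±55.8 (4.40±0.63, adjusted p = 8.75e-06). CHMP4C rose from 1.75 to 281±26.7 (6.78±1.11, adjusted p = 7.59e-05). The neural intermediate filament NES rose from 3439±592 to 8049±1490 (1.24±0.22, adjusted p = 0.000237) and the growth-cone protein GAP43 from 24.0±4.98 to 213±49.8 (3.11±0.56, adjusted p = 0.000264). GTSF1, a partner of piRNA silencing, fell from 2145±204 to 11.23±10.9 (-7.82±0.49, adjusted p = 1.14e-13), and the drug exporter ABCB1 fell from 328 to 12.4 (-5.37±0.84, adjusted p = 3.82e-05). The receptor kinase KIT fell from 417±39.7 to 105±60.5 (-2.16±0.34, adjusted p = 3.71e-05; -1.40 without line 2). FOS, an immediate-early transcription factor, fell from 941±637 to 31.2±19.3 (-4.37±0.48, adjusted p = 5.68e-08), and so did EGR1, from 381±207 to 141±44.4 (-1.14±0.25, adjusted p = 0.00263). Of genes that counter oxidants, NQO1 rose from 3201±674 to 4396±363 (0.50±0.11, adjusted p = 0.00341) and GSTM2 from 59.5±4.86 to 211±68.6 (1.75±0.28, adjusted p = 4.18e-05).

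Over all genes 609 rose and 490 fell in neil123 (138 and 173 of them 2-fold or more; with columns scaled to equal totals 481 rose and 587 fell), and 13232 did not pass. GCLC, GCLM, GSS, SLC7A11, GPX4 and GSR did not pass. Cholesterol synthesis genes were placed higher by camera (adjusted p = 0.000122, and adjusted p = 0.574 with an estimated correlation; 2 of 24 rose, 11 when adjusted over the list alone), and so were thioredoxin and peroxiredoxin genes (adjusted p = 0.0371, and adjusted p = 0.574 with an estimated correlation; 4 of 20 rose, 5 over the list alone). Immediate-early genes were placed lower (adjusted p = 0.00803, and adjusted p = 0.574 with an estimated correlation; 4 of 20 fell, FOS, FOSB and EGR1 among them, and 1 rose and 6 fell when adjusted over the list alone), as were ATF4 targets (adjusted p = 0.0136, and adjusted p = 0.992 with an estimated correlation; 0 of 37). Without line 1 the count of 1099 was 665 and without line 2 it was 539. Of 74 named genes called, 45 kept the call whichever of 11 libraries was left out, those of the paragraph above included. With 1 mean per line the count was 278, and CHMP4C, GAP43 and EGR1 lost their call.

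Several changes recurred across knockouts. Among genes higher in all 4 knockouts were KCTD11, TMEM35A and NME3, and lower in all 4 were TCEAL8, FASTKD2 and RTL8B, the last uncertain because of its copies. KCTD11, a ubiquitin ligase adaptor, averaged 11.8 and 29.9 in unlettered and lettered wt media libraries and 72.4 to 265 in the knockouts. FASTKD2 averaged 34.1±26.9 and 47.1±36.9 in wt (lowest library 6.59) and 1.94 to 3.50 in the knockouts. All of these calls held whichever library was left out in neil2, neil3 and neil123, and those of TCEAL8 and RTL8B in neil1 too. KCTD11 lost its neil1 call without wt 1.1, wt p1 or neil1 rep12 (1.55 to 2.13) and NME3 without neil1 rep13.2 (0.60). FASTKD2 lost it without wt 1.1, wt p1 or any neil1 library (-3.46 to -2.77). TMEM35A lost it without wt 1.1, wt p1, neil1 rep13.1 or rep13.2 (0.77 to 0.91). With 1 mean per line only TCEAL8 and RTL8B kept all 4 calls, FASTKD2 kept that in neil2, and the others those in neil2 and neil123. Called alike in 2 or more knockouts were 165 genes higher and 181 lower. Simulated unchanged groups sharing wt libraries gave means of 96.9 and 97.9, at most 123 and 117. With separate wt controls for each label set, 66 and 56 genes were called alike (simulated means 24.7 and 28.7, at most 35 and 38). Whether exon length trends add to the overlaps was not tested. The largest pair was neil2 with neil123: 137 genes higher and 159 lower in both, where independent lists would share 28.6 and 28.5 and the simulation 70.3 and 71.9. CHMP4C and TMEM47 were among the genes higher in both. Across genes, which are not independent replicates, the log2 changes of neil2 and neil123 correlated with r = 0.396 (simulated 0.216; covariance 0.0844, simulated 0.0113; r = 0.381 with separate wt controls), and those of neil1 and neil123 with r = 0.441 (simulated 0.213; covariance 0.0586, simulated 0.0110; r = 0.410 with separate wt controls). The other pairs had an r no higher than the simulated one. It was 0.405 against 0.407 for neil1 and neil2 (covariance 0.0526, simulated 0.0225) and 0.102 against 0.209 for neil1 and neil3 (0.00883, simulated 0.0108). It was 0.175 against 0.214 for neil2 and neil3 (0.0243, simulated 0.0111) and 0.248 against 0.461 for neil3 and neil123 (0.0352, simulated 0.0224). The simulation thus did not match all pairs. With separate wt controls r was 0.0697 for neil1 and neil3 and 0.1545 for neil2 and neil3. It was 0.187 and 0.136 for neil3 and neil123 set against different wt lines.

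BSO changed the expression of stress and glutathione genes in wt cells. HMOX1 (chr22, 35381096, 35394207), a heme oxygenase controlled by NRF2, rose from 565±70.7 to 2766±743 (2.26±0.12, adjusted p = 7.77e-16, n = 7 and 7), and NQO1 (chr16, 69709401, 69726560) rose from 2834±666 to 6673±1259 (1.25±0.09, adjusted p = 7.2e-12). SLC7A11 (chr4, 138164097, 138242349), the cystine importer, rose from 2130±411 to 4741±1051 (1.15±0.13, adjusted p = 1.04e-07), and GCLM (chr1, 93885199, 93909430), the modifier subunit of the enzyme BSO inhibits, from 1161±80.5 to 1698±195 (0.54±0.07, adjusted p = 4.52e-07). GCLC (chr6, 53497341, 53545101), its catalytic subunit, did not pass by limma but did with the replicate block, with line as a random block and with only the compared groups (1639±186 to 1858±124; 0.19±0.07, adjusted p = 0.08, paired adjusted p = 2.95e-05, range over alternatives 2.95e-05 to 0.16). Among ATF4 targets, the glutathione-degrading CHAC1 rose from 491±122 to 1754±438 (1.82±0.22, adjusted p = 2.74e-07), the mTORC1 inhibitor DDIT4 from 554±184 to 1691±350 (1.65±0.21, adjusted p = 8.61e-07) and the stress cytokine GDF15 from 32.4±11.9 to 169±78.6 (2.27±0.28, adjusted p = 3.61e-07). PMAIP1, the pro-apoptotic NOXA, rose from 691±130 to 992±154 (0.53±0.08, adjusted p = 9.94e-06). Of 24 cholesterol synthesis genes 13 fell and 1 rose (adjusted p = 0.0863 for the list with an estimated correlation). Among them HMGCS1 fell (4858±469 to 3348±422; -0.54±0.10, adjusted p = 0.000178) and so did SQLE (5626±712 to 4420±813; -0.36±0.05, adjusted p = 1.68e-05). ACSL4, which loads polyunsaturated fatty acids into lipids that ferroptosis oxidizes, also fell (-0.32±0.07, adjusted p = 0.00193). NEIL1, NEIL2 and NEIL3 did not pass with BSO in wt.

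**Figure D4:**
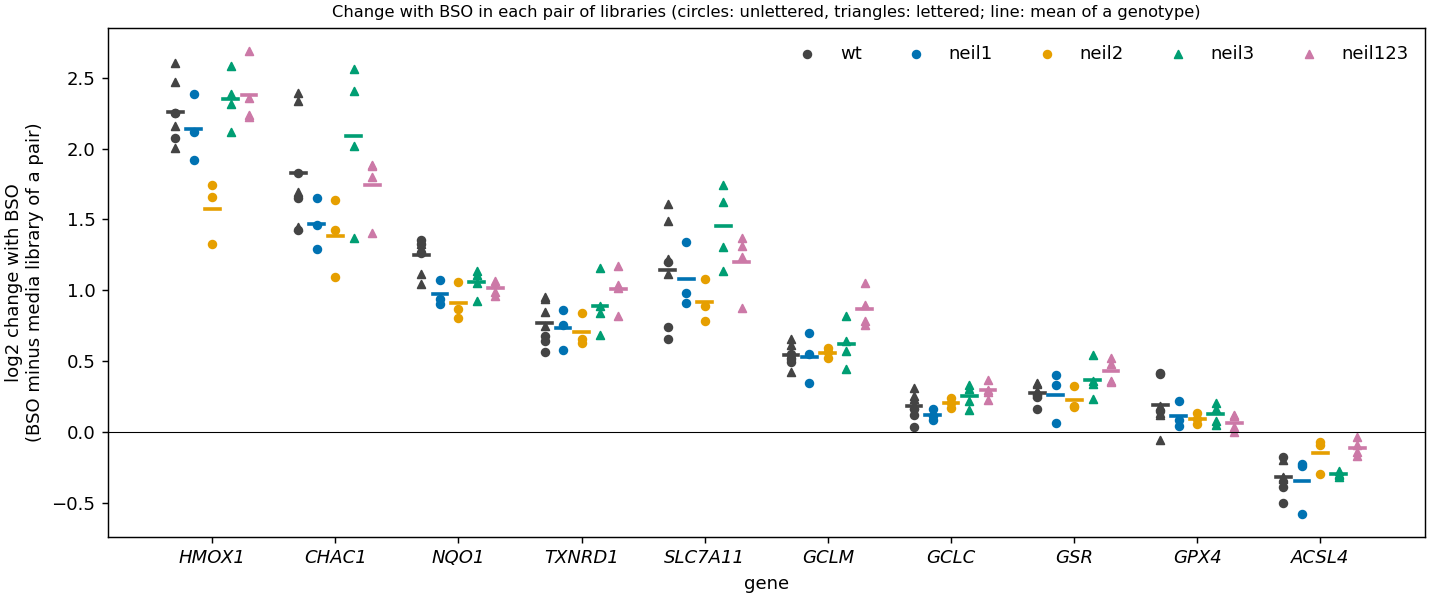
Log2 change with BSO (vertical axis: BSO library minus media library of the same replicate name) of 10 glutathione and stress genes; each point is 1 pair of libraries, coloured by genotype, circles for the unlettered and triangles for the lettered set, and lines are means of a genotype. HMOX1, CHAC1, NQO1, TXNRD1, SLC7A11 and GCLM lie above 0 in all 21 pairs, and the mean of HMOX1 is 1.58 in neil2 against 2.14 to 2.38 in the other genotypes.

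In wt 1038 genes rose and 900 fell with BSO (45 and 2 of them 2-fold or more; 855 and 1258 with columns scaled to equal totals), and 12393 did not pass. Paired by a replicate block, 2297 rose and 2232 fell. Of 11 genes of glutathione synthesis and cystine import 6 rose (7 adjusted over the list alone; camera adjusted p = 3.84e-07, and adjusted p = 0.000472 with an estimated correlation), of 30 NRF2 targets 23 (27 over the list alone; adjusted p = 5.31e-30, estimated 0.000472) and of 37 ATF4 targets 35 (35; adjusted p = 4.18e-53, estimated 0.00573). Pentose phosphate and NADPH genes (9 rose and 2 fell of 16; adjusted p = 3.48e-05, estimated 0.0181) and pro-apoptotic BCL2 genes (4 of 12 rose, 5 over the list alone; adjusted p = 0.00563, estimated 0.0181) also held with an estimated correlation. With the replicate block as well, NRF2 targets alone held at an estimated correlation (adjusted p = 0.0267). The glutathione (0.05075), ATF4 (0.0623), pentose phosphate and BCL2 lists (0.14 each) did not. Higher only with the preset correlation were the mitochondrially encoded subunits (7 of 13, 7 adjusted over the list alone; adjusted p = 1.39e-05, and adjusted p = 0.323 with an estimated correlation) and thioredoxin and peroxiredoxin genes (7 of 20, 8 over the list alone; adjusted p = 1.39e-05, and adjusted p = 0.052 with an estimated correlation). So were glutathione peroxidases and reductases (7 of 12, 7 over the list alone; adjusted p = 0.00109, and adjusted p = 0.233 with an estimated correlation) and p53 targets (5 of 25, 5 over the list alone and 11 with the replicate block; adjusted p = 0.00733, and adjusted p = 0.358 with an estimated correlation). Lower in the same way were cholesterol synthesis (13 fell and 1 rose of 24, 15 and 1 over the list alone; adjusted p = 1.57e-11, and adjusted p = 0.0863 with an estimated correlation), fatty acid (6 fell and 1 rose of 19, 6 and 1 over the list alone; adjusted p = 0.0061, and adjusted p = 0.268 with an estimated correlation) and heat shock genes (5 fell of 15, 8 over the list alone and 12 with the replicate block; adjusted p = 0.000154, and adjusted p = 0.264 with an estimated correlation). Base excision repair genes as a list did not stand apart (1 rose and 2 fell of 26, LIG3 by -0.21; adjusted p = 0.509). Of 109 named genes called, 86 kept the call whichever of 14 libraries was left out; MKI67 and GPX4 did not, MKI67 losing its call without wt media or BSO library 1.1 or 1.3 (-0.27 to -0.26) and GPX4 without any of those or media library 1.3A (0.17 to 0.18).

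The label sets of wt, compared with the replicate block, differed in part of the response. In 3 unlettered pairs 1344 genes rose and 1118 fell, in 4 lettered pairs 1363 rose and 1482 fell, and of 939 called in both sets 891 (94.9%) had the same direction, where independent lists would share 243; the log2 changes correlated with r = 0.403 across genes, which are not independent replicates. HMOX1 (2.19 unlettered, 2.31 lettered), NQO1 (1.31 and 1.20), CHAC1 (1.64 and 1.97) and GCLM (0.52 and 0.56) rose in both sets, and the differences did not pass (adjusted p of 0.26 to 0.751). SLC7A11 (0.87 and 1.36, adjusted p = 0.0323) and TXNRD1 (0.63 and 0.87, adjusted p = 0.0363) were among 788 genes whose response differed, as was CENPF, a kinetochore protein of dividing cells (-0.51 and 0.01, adjusted p = 0.0137). The change with BSO followed exon length in the unlettered pairs 1.1 (Spearman's rho across genes -0.378) and 1.3 (-0.324), and not in p1 (-0.0274); the other 18 pairs lay between -0.147 and 0.117.

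**Figure D5:**
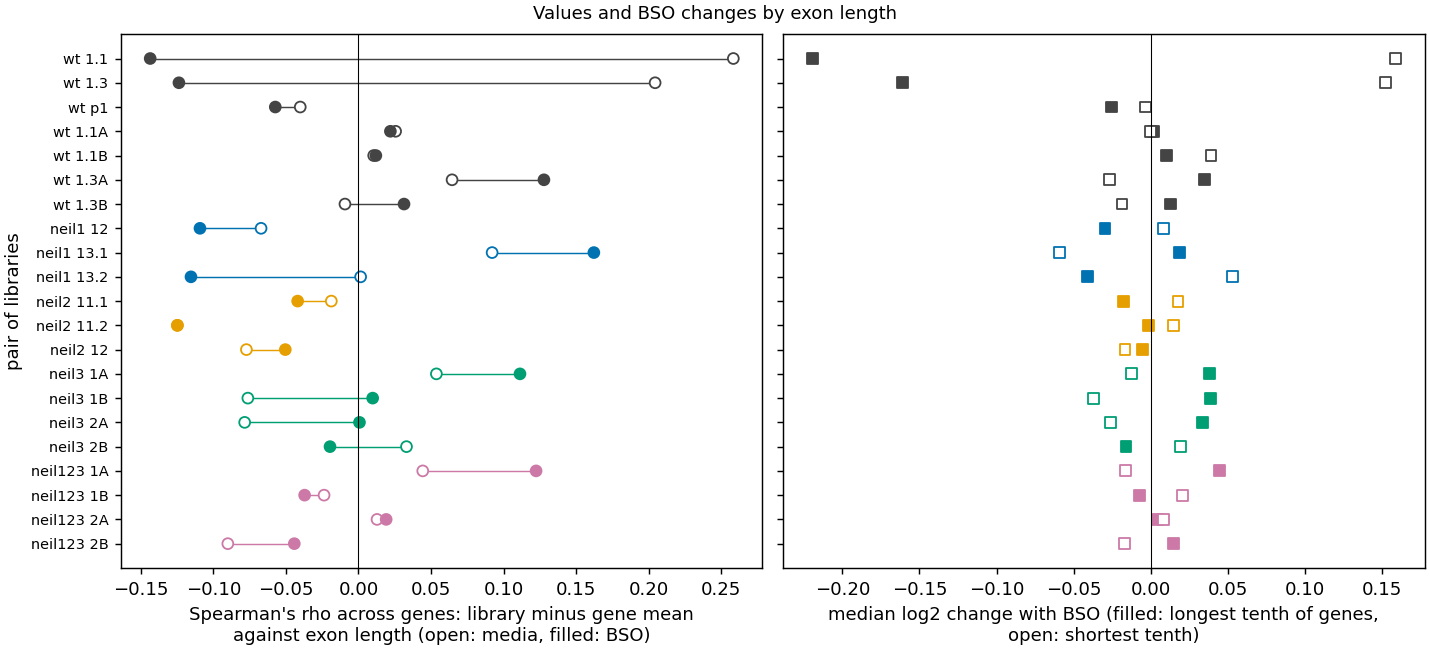
Left, Spearman's rho across genes between exon length and a library's log2 value minus the gene mean (horizontal axis; open for media, filled for BSO) for each of 21 pairs of libraries (vertical axis); right, median log2 change with BSO of the longest 10% (filled) and shortest 10% (open) of genes in the same pairs. In wt 1.1 and wt 1.3 rho is 0.258 and 0.204 in the media library and -0.144 and -0.124 in the BSO library, and the longest genes change by -0.22 and -0.16 against 0.16 and 0.15 for the shortest.

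BSO in cells labelled neil1 raised the same oxidant-response genes. HMOX1 rose from 524.5±19.4 to 2327±293 (2.14±0.18, adjusted p = 1.66e-09, n = 3 and 3), NQO1 from 3467±134 to 6806±566 (0.97±0.14, adjusted p = 0.000138), and SLC7A11 from 2407±313 to 5083±574 (1.08±0.20, adjusted p = 0.00311). The oxidant-induced growth inhibitor OSGIN1 rose from 470.1±132 to 1323±327 (1.498±0.24, adjusted p = 0.000581) and the ferritin heavy chain FTH1, which stores iron, from 9126±1603 to 17332±2770 (0.93±0.14, adjusted p = 0.000166). GCLM rose by 0.53±0.10 (adjusted p = 0.00481), a call lost without BSO library rep13.1 (0.42). Over all genes 118 rose and 46 fell (18 and 0 of them 2-fold or more; 124 and 79 with columns scaled to equal totals), and 14167 did not pass. The paired fit with a replicate block gave 589 and 506. By list, 12 of 30 NRF2 targets rose (20 adjusted over the list alone, 19 with the replicate block; camera adjusted p = 5.61e-29, and adjusted p = 0.00119 with an estimated correlation), 25 of 37 ATF4 targets (34 rose and 1 fell over the list alone; adjusted p = 5.7e-50, estimated 0.00794) and 5 of 11 glutathione synthesis and cystine import genes (adjusted p = 4.61e-06, estimated 0.00173). 8 of 24 cholesterol synthesis genes fell (16 over the list alone, 17 with the block; adjusted p = 4.55e-21, estimated 0.0149, and 0.0988 when estimated with the block). Mitochondrially encoded subunits rose as a list (6 of 13, 12 over the list alone, 11 with the block; adjusted p = 9.78e-19, and adjusted p = 0.0527 with an estimated correlation). The count of 164 became 26 without BSO library rep12, 64 without media library rep13.1 and 70 without media library rep13.2, and 5 of 39 named calls (HMOX1, NQO1, SLC7A11, FTH1 and OSGIN1) held whichever of 6 libraries was left out.

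Fewest genes passed in neil2 with BSO, HMOX1, NQO1 and FTH1 among them. HMOX1 rose from 418±78.2 to 1259±303 (1.58±0.18, adjusted p = 5.3e-06, n = 3 and 3), NQO1 from 3237±376 to 6069±235 (0.91±0.14, adjusted p = 0.000638) and FTH1 from 8493±1049 to 14772±1387 (0.80±0.14, adjusted p = 0.00281). GCLM also rose (1085±47.9 to 1600±39.9; 0.56±0.10, adjusted p = 0.00691), a call lost without media library rep11.2 (0.52) or BSO library rep12 (0.55). CHAC1 (1.38±0.34, adjusted p = 0.0852) and TXNRD1 (0.71±0.17, adjusted p = 0.081) did not pass by limma but did by DESeq2, with line as a random block and with the replicate block (paired adjusted p = 5.24e-06 and 5.3e-07; range over alternatives 5.24e-06 to 0.547 and 5.3e-07 to 0.169). In all 20 genes rose and 2 fell (2 and 0 of them 2-fold or more; 16 and 9 with columns scaled to equal totals), and 14309 did not pass. With the replicate block 529 rose and 297 fell. Of 30 NRF2 targets 6 rose (17 adjusted over the list alone, 18 with the replicate block; camera adjusted p = 1.23e-24, and adjusted p = 0.00355 with an estimated correlation), of 11 glutathione synthesis and cystine import genes 2 (3, 6 with the block; adjusted p = 0.00111, estimated 0.0399, and 0.124 when estimated with the block), and of 37 ATF4 targets 2 (30 over the list alone, 32 with the block; adjusted p = 1.07e-32, and adjusted p = 0.0549 with an estimated correlation). Cholesterol synthesis genes were lower as a list (0 of 24 passed over all genes, 8 fell over the list alone and 13 with the block; adjusted p = 7.18e-13, and adjusted p = 0.106 with an estimated correlation). Base excision repair genes were too (0 of 26, 1 fell with the block; adjusted p = 0.0208, and adjusted p = 0.225 with an estimated correlation). The count of 22 became 14 without BSO library rep11.1, 8 without media library rep11.1, 12 without media library rep11.2 and 4 without BSO library rep12. HMOX1, NQO1 and FTH1 were the 3 of 11 named calls that held whichever of 6 libraries was left out.

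BSO raised oxidant-response genes in neil3 as well. HMOX1 rose from 573±91.4 to 2942±584 (2.35±0.16, adjusted p = 1.51e-12, n = 4 and 4), SLC7A11 from 1853±124 to 5165±1167 (1.45±0.17, adjusted p = 1.12e-06), GCLM from 1196±94.7 to 1851±281 (0.62±0.09, adjusted p = 1.68e-05) and CHAC1 from 429±132 to 1769±169 (2.09±0.29, adjusted p = 1.22e-05). PMAIP1 rose by 0.62±0.10 (adjusted p = 0.000112) and the leucine sensor SESN2 from 1486±105 to 3226±301 (1.12±0.16, adjusted p = 1.46e-05). The chaperone HSP90AA1 fell by -0.41±0.07 (adjusted p = 0.000112) and the mitochondrial carrier UCP2 by -0.64±0.11 (adjusted p = 0.000135). NEIL3 was higher with BSO (520±106 to 649±87.2; 0.33±0.10, adjusted p = 0.0323), a call lost without BSO library 1A (0.29), 2A (0.28) or 2B (0.33) or media library 1A (0.27) or 1B (0.23). Over all genes 481 rose and 418 fell (55 and 0 of them 2-fold or more), and 13432 did not pass. A replicate block raised these to 1410 and 1512. Of 30 NRF2 targets 20 rose (25 adjusted over the list alone; camera adjusted p = 1.27e-30, and adjusted p = 0.0008 with an estimated correlation), of 37 ATF4 targets 35 (35; adjusted p = 4.29e-61, estimated 0.00258), and of 11 glutathione synthesis and cystine import genes 5 (6; adjusted p = 1.66e-06, estimated 0.00104). Of 12 pro-apoptotic BCL2 genes 4 rose (adjusted p = 0.0149, estimated 0.0428, and 0.14 when estimated with the block), and of 24 cholesterol synthesis genes 17 fell (18; adjusted p = 3.81e-15, estimated 0.0478, and 0.201 when estimated with the block). The base excision repair list was lower (1 rose and 4 fell of 26; adjusted p = 0.0149, and adjusted p = 0.144 with an estimated correlation). The count of 899 became 588 without media library 1A, 595 without media library 2A and 599 without BSO library 2B. Of 73 named genes called 48 kept the call whichever of 8 libraries was left out.

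BSO raised oxidant-response genes in cells labelled neil123 too. GCLM had its largest rise here, although the difference from wt did not pass. HMOX1 rose from 465±51.5 to 2425±324 (2.38±0.16, adjusted p = 1.07e-12, n = 4 and 4), NQO1 from 4396±363 to 8902±995 (1.01±0.12, adjusted p = 1.14e-06), GCLM from 1111±104 to 2028±66.5 (0.87±0.09, adjusted p = 7.17e-08) and SLC7A11 from 1741±159 to 4063±881 (1.20±0.17, adjusted p = 4.68e-05). Also higher were glutathione reductase GSR (4016±109 to 5413±357; 0.43±0.08, adjusted p = 0.00165), the thioredoxin reductase TXNRD1 (1.01±0.15, adjusted p = 5e-05), the pentose phosphate enzyme TKT (0.39±0.05, adjusted p = 6.16e-06) and CHAC1 (305±61.3 to 1041±310.1; 1.74±0.29, adjusted p = 0.00046). The death receptor TNFRSF21 fell from 231 to 162 (-0.51±0.09, adjusted p = 0.00126). GCLC passed here only with the replicate block or with line as a random block (0.29, adjusted p = 0.136, paired adjusted p = 8.44e-06, range over alternatives 8.44e-06 to 0.699). Over all genes 191 rose and 39 fell (34 and 2 of them 2-fold or more), and 14101 did not pass. In the paired fit with a replicate block 795 rose and 475 fell. Of 30 NRF2 targets 19 rose (24 adjusted over the list alone; camera adjusted p = 7.41e-51, and adjusted p = 1.15e-05 with an estimated correlation), of 37 ATF4 targets 24 (34; adjusted p = 6.1e-49, estimated 0.00685, and 0.0603 when estimated with the block), and of 11 glutathione synthesis and cystine import genes 5 (6; adjusted p = 1.15e-07, estimated 0.000275). Of 16 pentose phosphate and NADPH genes 5 rose (7; adjusted p = 1.22e-06, estimated 0.00685, and 0.0792 when estimated with the block). The cholesterol list was lower with the preset correlation alone (1 of 24 fell, 6 over the list alone, 10 with the block; adjusted p = 5.71e-08, and adjusted p = 0.248 with an estimated correlation). The mitochondrially encoded list did not pass (0 of 13; adjusted p = 0.912). The count of 230 became 113 without BSO library 1A, 103 without BSO library 1B and 129 without media library 2A. Of 41 named genes called 23 kept the call whichever of 8 libraries was left out.

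With 1 mean per line BSO changed 60 genes in neil1, 11 in neil2, 241 in neil3 and 28 in neil123. Calls then lost included those of SLC7A11 in neil2, NEIL2 and NEIL3 in neil3, and NEIL2, CHAC1 and TNFRSF21 in neil123.

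A common response to BSO ran through all genotypes. Higher in all 5 were 17 genes, among them HMOX1, NQO1, SLC7A11, GCLM and FTH1. TNFRSF21 alone was lower in all 5. These were 217 and 71 genes with the replicate block. HMOX1, NQO1 and FTH1 kept their call in every genotype whichever library was left out. Of the 1938 genes called in wt, the change had the same sign in 98.5% in neil1, 87.8% in neil2, 96.4% in neil3 and 93.6% in neil123. Called in wt and in the knockout were 161, 22, 690 and 207 genes, none in opposite directions, where independent lists would share 22.2, 2.98, 122 and 31.1. Across genes, which are not independent replicates, the log2 changes correlated with those of wt with r = 0.610, 0.462, 0.678 and 0.563.

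Whether the response to BSO differed between the knockouts and wt was tested as the difference between the change in a knockout and that in wt. By limma 0 genes passed in neil1, neil2, neil3 and neil123, with 135, 662, 378 and 496 genes at an unadjusted p under 0.05 where 716.55 would arise by chance. EdgeR also gave 0 in each and DESeq2 0, 0, 0 and 1. HMOX1 rose less in neil2 than in wt by -0.68±0.22 and NQO1 by -0.33±0.17, which passed only with the replicate block (adjusted p = 1 for each, paired adjusted p = 0.0249 and 0.0305, range over alternatives 0.0249 to 1 and 0.0305 to 1). In that fit, whose wt pairs are of both label sets, 11 genes differed upward and 20 downward in neil2 and 0 in the other knockouts. With only wt pairs of the same label set it gave 137 in neil2 and 6 in neil123. The 31 became 84 with the exon length trend removed and 280 without the unlettered wt libraries 1.1 and 1.3. They became 55 without wt 1.1, 4 without wt 1.1A, 185 without wt 1.1B, 17 without wt 1.3, 7 without wt 1.3A, 6 without neil2 rep11.1, 6 without neil2 rep11.2 and 9 without neil2 rep12. Without a call, GCLM differed by 0.33±0.11 in neil123 (adjusted p = 0.999), NEIL3 by 0.36±0.12 in neil3 (adjusted p = 1) and CHAC1 by -0.36±0.40 in neil1 (adjusted p = 1).

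As lists, ATF4 targets responded less than in wt in neil1 (camera adjusted p = 5.69e-05, and adjusted p = 0.501 with an estimated correlation), neil2 (adjusted p = 1.82e-14, and adjusted p = 0.455 with an estimated correlation) and neil123 (adjusted p = 8.35e-09, and adjusted p = 0.728 with an estimated correlation). NRF2 targets responded less in neil1 (adjusted p = 0.0321, and adjusted p = 0.501 with an estimated correlation) and neil2 (adjusted p = 0.000266, and adjusted p = 0.467 with an estimated correlation), and glutathione synthesis and cystine import genes less in neil2 (adjusted p = 0.00902, and adjusted p = 0.175 with an estimated correlation). The mitochondrially encoded subunits responded more in neil1 (adjusted p = 7.9e-10, and adjusted p = 0.355 with an estimated correlation) and less in neil123 (adjusted p = 9.44e-08, and adjusted p = 0.728 with an estimated correlation). In neil123 p53 targets (adjusted p = 0.00314, and adjusted p = 0.728 with an estimated correlation) and pro-apoptotic BCL2 genes (adjusted p = 0.0256, and adjusted p = 0.158 with an estimated correlation) responded less, and cholesterol synthesis genes fell less (adjusted p = 0.0236, and adjusted p = 0.728 with an estimated correlation). With the replicate block NRF2 targets (adjusted p = 0.0315, and 0.766 when estimated with the block) and heat shock genes (adjusted p = 0.000706, estimated 0.7332) also passed upward in neil123. Glutathione synthesis and cystine import genes passed downward in neil1 (adjusted p = 0.0441, estimated 0.399). Further lists responded less in neil1: thioredoxin and peroxiredoxin genes (adjusted p = 0.0384, and adjusted p = 0.355 with an estimated correlation), ferroptosis suppressors, unfolded protein response chaperones and glycolysis and hypoxia genes (each adjusted p = 0.0218, and adjusted p = 0.355 with an estimated correlation), while cholesterol synthesis genes fell more (adjusted p = 0.00331, and adjusted p = 0.454 with an estimated correlation). No member of these lists passed by itself, over all genes or adjusted over the list alone, but with the replicate block 2 NRF2 targets, 1 ATF4 target and 1 glutathione synthesis and cystine import gene were lower in neil2. In neil3 0 lists were called.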

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

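Tests chosen only after the results were seen are those of exon length and of chromosome 15, the tests of the label set and of NEIL loss for the genes shared by the knockouts, and the paired comparisons between label sets. The splits of the libraries, the shared wt libraries and the copies of RTL8B were to be tested from the start.

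Some libraries lay far from the others of their group. Mitochondrially encoded genes took 4.1345% of the reads in wt BSO 1.3 (others 2.64 to 3.24), 2.00822% in neil3 media 1A (others 2.34 to 2.37) and 1.85587% in neil123 media 1A (others 2.48 to 2.58). Genes with reads numbered 18264 in neil3 media 1B, against about 18400 in the others of that group. NEIL2 stood at 308.523 in neil3 BSO 1A (others 339 to 343), and GSS, glutathione synthetase, at 2229.31 in neil3 BSO 1B (others 2130 to 2150). Chance sets a library apart in about 1 in 20 groups, and 114 combinations of group and measure (19 measures) were looked at, so these 6 are about what chance gives.

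With the replicate block 31 genes, HMOX1 and NQO1 among them, passed for a different response to BSO in neil2 and wt, a count that chance also gives (8 of 100 splits) and that ranged from 4 without wt 1.1A to 185 without wt 1.1B. In the label sets of wt 788 genes, SLC7A11, TXNRD1 and CENPF among them, passed for a different response. Entries without a gene symbol, of which 2308 were tested and which no comparison of the report uses, passed the threshold in 2 (neil1), 25 (neil2), 2 (neil3) and 44 (neil123) cases in media, in 62 (wt), 6 (neil1), 1 (neil2), 16 (neil3) and 13 (neil123) cases with BSO, and in 1 case as a different response in neil1.

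Long genes were lower with BSO in the unlettered wt pairs 1.1 and 1.3. A trend with length after BSO in most pairs is excluded, since the median rho over the other pairs was 0.0027. The other unlettered pairs showed no such trend over all genes either (median rho -0.0274). The mean change of 8 long genes was -0.36 to 0.0232 in these pairs and -0.0067 to 0.190 in the lettered pairs. They (SYNE2 among them) were picked after the values were seen, so an effect of the label set on some long genes stays undecided. RNA quality or preparation of the libraries of pairs 1.1 and 1.3 remains a candidate explanation: their media libraries had rho of at least 0.2044 with exon length, against at most 0.1622 in the other 40 libraries. With the block and with the trend removed, 4574 genes passed for BSO in wt against 4529 before, and of 113 named values, HMOX1 and NQO1 among them, 112 stayed on the same side of the threshold as by limma without either, while GCLC gained a call. With the trend removed and no block LIG1 lost its call and GCLC gained one. No biological explanation was tested beyond BSO itself.

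Genes of distal chromosome 15 were lower in neil1 line 12. Library size or normalization is excluded, since genes of other chromosomes shifted by no more than 0.0306, and so is an effect common to the label set (lowest median in its other 3 lines -0.0056). Loss of 1 copy of the region in part of the cells stays open: HAP1 is known to carry an extra copy of a stretch of chromosome 15 (taken as 61 to 89 Mb), so that such a loss would lower genes outside that stretch more, and the median outside was lower than inside by -0.1501 in media and -0.1159 with BSO. A smaller difference of this kind (-0.0663 and -0.0809) was present in neil2 line 11, whose distal chromosome 15 was not lower (0.0195 and 0.0308), so that it does not by itself mark such a loss. NEIL1 lies inside the stretch, and its level of 284 in line 12 might follow in part. Whether this arose with the edit of the line was not tested.

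TCEAL8, FASTKD2 and RTL8B were lower and KCTD11 higher in all 4 knockouts. A batch effect of the label set cannot be judged, since calls in both sets had picked the genes. With BSO all 4 had no overlap in either set between knockout and wt libraries. For independent libraries chance gives this in a given direction in 1.19% (unlettered) and 0.202% (lettered) of cases. Each BSO library is paired with a media library that helped pick the genes, so chance gives more here. Chance shared through the same wt libraries stays open for each gene: 3 of the 4 were called in a knockout of each set against separate wt libraries, but calls against these very libraries had picked them. Over all genes 7 were called alike in all 4 knockouts, where the simulated unchanged groups gave a mean of 0.5 and at most 2. Whether RTL8B lost reads to RTL8A and RTL8C stays open: the sum of these genes differed from wt by at most 0.3295 over the knockouts. Loss of a NEIL gene might itself be the cause, but 0 knockout lines had the wt level of 2 or more of the 4 genes, and no edited control line is present, so that it cannot be told apart from what cloning and editing bring. All 8 knockout lines, neil1 and neil2 included, share the pattern.

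The libraries of each comparison were also split in other ways. For neil1 in media chance cannot be excluded: 6 of 100 splits gave as many genes as the real 50. The highest of the others, which put wt 1.1 and 1.3 with neil1 rep13.2, gave 802, several times the real count, which points to a structure of the samples beyond genotype. Splits over wt libraries of both sets rarely gave as many for neil2 in media (1 of 100: 1508, highest other 763). This held for neil3 (3 of 100: 83, highest other 863) and neil123 (1 of 100: 1099, highest other 183) too. Libraries of a line correlate, however (0.206), and a knockout is of 1 set, so chance is not excluded. With 1 mean per line 10, 828, 13 and 278 genes passed in neil1, neil2, neil3 and neil123, and splits of whole lines are too few for a share under 0.05. The split with 863 genes follows the letters A and B of the names, again several times the real count, and with the letter as a block 100 genes passed for neil3. For BSO in wt chance can be excluded (1 of 64 splits of the pairs; 1938, highest other 895). The splits of pairs are too few in neil1 (1 of 4; 164, highest other 0), neil2 (1 of 4; 22, highest other 0), neil3 (1 of 8; 899, highest other 0) and neil123 (1 of 8; 230, highest other 0). Splits that do not part the pairs gave up to 430 genes in neil1 with the libraries of line 12 together, 493 in neil2 and 1058 in neil3 for line 1 against line 2, more than the unpaired counts for BSO and fewer than those with the replicate block (1095, 826 and 2922). For the differences in response, by limma, the real count was 0 and all 100 of 100 splits gave as many (highest others 186, 128, 37 and 1 for neil1, neil2, neil3 and neil123). For the 31 genes of neil2 with the block chance cannot be excluded (8 of 100; highest other 2069, again a structure of the samples).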

How the results depend on the processing

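Leaving out lines, leaving out the unlettered wt libraries 1.1 and 1.3, fitting each label set of wt alone, removing the exon length trend, pairing with only wt pairs of the same label set, and the replicate block in tests of lists were chosen after the results were seen. Over all alternatives 17121 values of named genes stayed on the same side of the threshold, 2186 lost and 93 gained a call, and 5 reversed. Where a value moved, the cause was not tested, except that fits of fewer libraries have fewer replicates by construction. Without line 13 of neil1 or line 11 of neil2, 1 library is left, taken to vary like the other groups.

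NEIL2 was lower in neil2 by -0.92 to -0.81 and in neil123 by -0.83 to -0.76 with each library left out. NEIL3 was lower in neil123 by -0.67 to -0.56. NEIL1 ranged from -0.09 to 0.33 in neil1 (-0.635 without the label set, -0.263 without line 13) and from 0.13 to 0.25 in neil123 (0.752 without the label set). NEIL3 in neil3 ranged from -0.43 to -0.23; it passed without the label set (-0.40), without media library 2A (-0.43) or 2B (-0.42), and without line 2 (-0.59), whereas without line 1 it was -0.083 (adjusted p = 0.889). Reversed values came without the label set for NEIL1 in neil2 (-0.0618), CSAD in neil2 (-0.2225) and EBP in neil123 (-0.0967), and for CENPF with BSO in wt (0.0073) in only lettered wt libraries, with or without the replicate block.

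In media the 50 genes of neil1 became 200 without the label set, 80 with the letter as a replicate block, 32 with the line as a random block, 10 with 1 mean per line, 18 with only the compared groups, 106 by DESeq2, 81 without line 12, 192 without line 13 and 21 without the unlettered wt libraries of lines 1.1 and 1.3; with single libraries left out they ranged from 19 to 57, moved by wt 1.1 (19), wt 1.3 (33), wt p1 (24), neil1 rep13.1 (23) and rep13.2 (25). The 1508 genes of neil2 became 2836 without the label set, 865 with the line as a random block, 828 with 1 mean per line, 226 with only the compared groups, 113 without line 11 and 801 without those wt libraries. Single libraries gave 306 to 1749. The 83 genes of neil3 became 13 with 1 mean per line, 131 by DESeq2, 159 without line 1 and 249 without line 2, and 63 to 83 with single libraries left out. The 1099 genes of neil123 became 278 with 1 mean per line, 665 without line 1 and 539 without line 2, and 785 to 1177 with single libraries left out.

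For BSO the replicate block raised each count, and removing the exon length trend as well, or leaving out the unlettered wt libraries of lines 1.1 and 1.3 as well, changed it further. In wt 1938 became 4529 with the block, 4574 and 3825 with those additions, 1046 without the label set, 1008 without those wt libraries alone, 1109 in only unlettered and 759 in only lettered wt libraries, and 1441 to 2022 with single libraries left out. In neil1 164 became 1095 with the block, 1409 and 1841 with the additions, 57 without the label set, 308 with the line as a random block, 60 with 1 mean per line, 2 with only the compared groups, 279 by DESeq2, 23 without line 12 and 6 without line 13. Single libraries gave 26 to 219. In neil2 22 became 826 with the block, 994 and 1420 with the additions, 8 without the label set, 77 with the line as a random block, 11 with 1 mean per line, 0 with only the compared groups (by limma, with 1015 genes at an unadjusted p under 0.05 and, over all groups, 25 called by edgeR), 83 by DESeq2, 4 without line 11 and 2 without line 12. Single libraries gave 4 to 24. In neil3 899 became 2922 with the block, 3371 and 3710 with the additions, 387 without the label set, 241 with 1 mean per line, 435 with only the compared groups, 191 without line 1 and 122 without line 2. Single libraries gave 588 to 895. In neil123 230 became 1270 with the block, 1476 and 1867 with the additions, 108 without the label set, 361 with the line as a random block, 28 with 1 mean per line, 20 without line 1 and 63 without line 2. Single libraries gave 103 to 230.

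The differences in BSO response stayed at 0 by limma with each library left out, with 135 to 662 genes at an unadjusted p under 0.05 over the 4 knockouts; edgeR gave 0 throughout, and DESeq2 gave 1 in neil123. For neil2 the replicate block gave 31, 84 with the exon length trend removed, 280 without those wt libraries and 137 with only wt pairs of its label set. Without line 11 the unpaired count was 2. The 31 ranged from 4 to 185 without single replicates, as above, and became 9 without line 12. For neil123 the block gave 3 with the trend removed and 6 with only wt pairs of its label set.

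Of 95 list calls over all comparisons, 22 held with an estimated correlation. The overlap of 346 genes called alike in 2 or more knockouts became 122 when the wt libraries of each label set served as separate controls (66 higher and 56 lower, simulated means 24.7 and 28.7). With the preset correlation the replicate block ended no list call in the BSO comparisons, and the lists and named genes it added there are given in the report or among the other observations. With an estimated correlation the block ended 10 of 20 list calls there: glutathione synthesis and cystine import in wt and neil2, ATF4 targets in wt and neil123, pentose phosphate genes in wt and neil123, pro-apoptotic BCL2 genes in wt and neil3, and cholesterol synthesis in neil1 and neil3 (adjusted p of 0.05075 to 0.201). NRF2 targets held in all 5 genotypes (0.00273 to 0.0336), glutathione synthesis and cystine import in neil1 (0.0493), neil3 (0.0368) and neil123 (0.0248), and ATF4 targets in neil1 (0.0493) and neil3 (0.0368). At this depth genes with a mean under 10 were not tested. In the simulations, whose libraries were independent unlike the real ones, 1.5-fold changes were found for 54 to 81 of 100 genes. A gene that did not pass is therefore not shown to be unchanged.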

Other observations

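The tests of chromosome regions and those of lists with the replicate block were chosen only after the results were seen.

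Some iron, metal, chaperone and glycolysis genes also passed with BSO. In wt 4 of 18 iron handling genes rose and 2 fell (7 and 3 adjusted over the list alone, 7 and 4 with the replicate block; camera adjusted p = 0.0257, and adjusted p = 0.323 with an estimated correlation), FTH1 (10653±2738 to 21339.5±6758, n = 7 and 7) and the light chain FTL (1.09±0.19, limma adjusted p = 8.81e-05) among those that rose. Of 6 metallothioneins, which share reads with their copies and are uncertain, 2 rose in wt (3 over the list alone, 5 with the block; adjusted p = 0.0119, and adjusted p = 0.323 with an estimated correlation). The endoplasmic reticulum stress gene HERPUD1 rose from 1545±138 to 2646±217 (0.78±0.08, adjusted p = 2.77e-08), 1 of 4 unfolded protein response chaperones of 21 that rose (5 over the list alone, 7 with the block; adjusted p = 0.0127, and adjusted p = 0.323 with an estimated correlation). VEGFA, the vascular growth factor, rose from 1527±276 to 2312±579 (0.58±0.07, adjusted p = 1.85e-07) among 9 glycolysis and hypoxia genes that rose and 2 that fell of 29 (9 and 2 over the list alone, 14 and 2 with the block; adjusted p = 0.005, and adjusted p = 0.268 with an estimated correlation). Of 14 glutathione transferases 3 rose in wt (4 over the list alone, 5 with the block; adjusted p = 0.0176, and adjusted p = 0.0903 with an estimated correlation).

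Some genes of DNA repair and methylation passed with BSO. TET1, which oxidizes methylated cytosine, fell in wt from 3130±601 to 2467±136 (-0.32±0.09, adjusted p = 0.00974), 1 of 3 that fell of 13 TET and DNA methylation genes, a list that passed only with the replicate block (camera adjusted p = 0.0648, paired 0.0457, and 0.1466 when paired with an estimated correlation). The ligase LIG3 fell from 2126±147 to 1831±79.5 (-0.21±0.03, adjusted p = 3.76e-05). NEIL2 passed downward with BSO in neil123 (-0.32±0.08, limma adjusted p = 0.0289) and neil3 (-0.28, adjusted p = 0.0288), and only with the replicate block in neil1 (-0.26, adjusted p = 0.221, paired 0.0302, range over alternatives 0.0302 to 0.99) and neil2 (-0.27, adjusted p = 0.315, paired 0.0303, range 0.0303 to 1). In neil3 the call was lost without BSO 1A or 2B or media 1B, 2A or 2B (-0.29 to -0.23). In neil123 and neil3 it was lost with 1 mean per line. In wt NEIL2 did not pass (-0.10, adjusted p = 0.332).

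Some glutathione and ferroptosis genes did not pass with BSO by limma but did with the replicate block, and GCLC in neil3, ACSL4 in neil1 and AIFM2 in neil2 and neil3 also with line as a random block. AIFM2 passed by DESeq2 in neil2 and neil3 and by edgeR in neil3. GCLC rose by 0.21±0.11 in neil2 (limma adjusted p = 0.675, paired 0.00633, range over alternatives 0.00633 to 1) and by 0.25±0.10 in neil3 (adjusted p = 0.114, paired 3.85e-05, range 3.85e-05 to 0.404). The glutathione reductase GSR rose in neil1 (0.26±0.09, adjusted p = 0.221, paired 0.0024, range 0.0024 to 0.577) and neil2 (0.23±0.09, adjusted p = 0.476, paired 0.0114, range 0.0114 to 0.88). ACSL4 fell in neil1 (-0.35±0.11, adjusted p = 0.121, paired 0.000297, range 0.000297 to 0.577). AIFM2, a reductase that protects against ferroptosis, rose in neil1 (0.21±0.07, adjusted p = 0.176, paired 0.00954, range 0.00954 to 0.639), neil2 (0.27±0.07, adjusted p = 0.13, paired 0.002, range 0.002 to 0.547) and neil3 (0.19±0.06, adjusted p = 0.0627, paired 0.00348, range 0.00348 to 0.232), and NEIL3 rose in neil123 (0.21±0.10, adjusted p = 0.429, paired 0.0399, range 0.0399 to 1).

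Further lists did not pass by limma but did with the replicate block, of which ferroptosis suppressors, the peroxidases and metallothioneins passed in another alternative as well: with BSO the glutathione transferases (0.0454) and ferroptosis suppressors (0.03) in neil2, glutathione peroxidases and reductases in neil3 (0.0407), metallothioneins in neil123 (0.0434), and endoderm and pluripotency markers, downward, in wt (0.0426), neil3 (0.0407) and neil123 (0.0403). With the block and an estimated correlation none of these 7 passed (adjusted p = 0.1318 to 0.431).

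Mitochondrially encoded genes took 2.44±0.198% of reads in wt media libraries and 3.18±0.464% with BSO (n = 7 and 7). The share was also higher with BSO in neil1, neil2 and neil3, whereas in neil123 it was 2.37% and 2.45%. Over 8 knockout lines, 5 of 1232 stretches of 20 Mb had a median log2 difference of 0.1 or more in size from wt in both media and BSO libraries: 2 on chromosome 15 in neil1 line 12, chromosome X from 80 Mb in neil2 line 11 (0.111 and 0.180), chromosome 3 from 160 Mb in neil2 line 12 (0.125 and 0.17) and chromosome 9 from 60 Mb in neil123 line 2 (0.127 and 0.158). In media the lines resembled neil123 to different degrees across genes, which are not independent: r with neil123 lines 1 and 2 was 0.464 and 0.441 for neil1 line 13, 0.163 and 0.0619 for neil1 line 12, 0.415 and 0.342 for neil2 line 11, and 0.164 and 0.136 for neil2 line 12. Line 12 of neil1 and of neil2 has 1 media library and the others 2, and the noise of a single library lowers r.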
